A study of Mus musculus and Homo sapiens with 10 samples.

How the data were processed

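Break ends were measured by in-suspension BLISS in 10 libraries: 4 of human TK6 cells (DMSO or etoposide) and 6 of mouse jejunal enterocytes sorted as Cd73 negative, mid or high. Per the labels' protocols, break ends were blunted and ligated to adapters, amplified by in vitro transcription and sequenced. Reads were aligned with BWA to GRCh37 or GRCm38, per the submitters' processing notes; the version, mapping quality filters and duplicate handling are not given in the sources used here. The deposited files list, for each library alone, chromosome, position and a count of break ends, not normalized and without strand. Whether a count is of unique molecular identifiers or of reads is not stated, so intervals and floors given here cover counting error only. The human files hold no mitochondrial positions and list 26, 2, 7001 and 10322 positions more than once, whose counts were added up. The mouse files list each position once and include mitochondrial DNA and unplaced contigs, which were left out of all tests since nuclear chromosomes were the subject.

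Nuclear depth ran from 585021 to 11467827 break ends in TK6 and from 1272771 to 13043514 in enterocytes. Positions with over 1 break end held 2.93% and 1.43% of break ends in DMSO, 12.3% and 20.0% after etoposide, 25.5% and 26.2% in Cd73 negative, 12.8% and 16.6% in mid, and 6.32% and 6.38% in high libraries. With all libraries of a species at equal depth, these were 2.21%, 1.43%, 1.25% and 2.95% in TK6 and between 4.66% and 6.38% in enterocytes.

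Counts were summed over non-overlapping bins of 100 kb in both species and, for mouse, over the bodies of protein-coding genes (21887 on the main chromosomes of GRCm38.p6, of which 3841 overlap another). The annotation gave no gene strand, and no human annotation and no genome sequence were used here, so TK6 was analysed in bins only. Counts were tested with edgeR 4.0.16 (R 4.3.3; TMM, filterByExpr, quasi-likelihood F test), and a Benjamini-Hochberg adjusted p under 0.05 was called. TK6 libraries were fitted alone, and all 6 enterocyte libraries in a single fit of 3 groups. CPM are counts per 1000000 of the TMM-scaled sum over the bins, or over gene bodies for genes; EPM are break ends per 1000000 of the unscaled library. Scaling by library size without TMM moved the median log2 fold change from 0.02 to -0.17 in TK6 bins and from -0.00217 to -0.13 in enterocyte genes (high against negative); changes are given relative to the TMM scaling.

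The 17 mouse gene lists were villus tip, mid-villus nutrient absorption, villus bottom antimicrobial, crypt stem cell, proliferation, enterocyte identity, goblet, Paneth, enteroendocrine, tuft, lymphocyte, stromal and endothelial, neuronal, common fragile site, immediate early, ribosomal protein and olfactory receptor genes. Lists, groups, main tests, most alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1, preset correlation 0.01) and adjusted over the 17 lists of a comparison, with an estimated correlation and fry as alternatives. Each list's median was also placed among 10000 random lists matched on gene length and density. Single values per library were compared by two-sided exact permutation tests, for which 2 against 2 libraries give at least 0.333.

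The rule named features past the threshold whose groups did not overlap (at most 10 by p and 5 by size in each direction for a main comparison), Nt5e, and up to 4 members per list with the smallest p. Naming up to 3 members of each list past the threshold, and other members past adjustment over the list alone, was chosen after values were seen, and not every member picked this way is named. The spacing measures, shares near gene ends and in gene bodies, bins for the further enterocyte comparisons, the length offset, the gene end windows and the gene bodies with 1 kb on each side were added after the files were seen. For spacing, 4 values in 3 comparisons were computed under 4 settings.

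The tests were tested on simulated counts with 200 changed features, 50 for each size. For TK6 bins (27972), 0%, 6%, 30% and 64% were recovered at 1.5, 2, 3 and 4-fold with 2 false calls; for enterocyte genes (17809), 12%, 46%, 76% and 88% with 2 false calls. The common dispersion was 0.0554 in TK6 bins and 0.00665 in enterocyte genes. Alternatives were DESeq2 1.42.0, library size scaling, no filter, each position counted once, thinning to the shallowest library, positions over 100 break ends left out, other bin sizes, gene bodies with 1 kb on each side, a replicate block, and each library left out in turn. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.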

Results

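DNA double-strand breaks were mapped across the genome with in-suspension BLISS, in which the ends of breaks are blunted and ligated to an adapter inside cells or nuclei, so that each sequenced end marks the position of a break. The series covers 10 libraries in 5 groups of 2. TK6, an established human lymphoblastoid cell line, was treated with DMSO, the vehicle, or with etoposide, a drug that traps topoisomerase II on cleaved DNA. Mouse jejunal enterocytes, the absorptive cells of the intestinal villus, had been sorted as negative, mid or high for Cd73, the ectonucleotidase encoded by Nt5e. Nuclear break ends numbered 1081859 and 585021 in the DMSO libraries and 11467827 and 8939870 in the etoposide libraries. The enterocyte libraries held 13043514 and 12585228 (Cd73 negative), 4757961 and 5160171 (Cd73 mid), and 1522615 and 1272771 (Cd73 high). The labels do not say whether the libraries of a group came from separate cultures or mice, so the tests below measure only the spread between these libraries, which can be technical. The edgeR tests take that spread partly or wholly from all bins or genes together.

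The first comparison asked how etoposide altered the break landscape of TK6 cells. The etoposide libraries held 10.6 times (replicate 1) and 15.3 times (replicate 2) the break ends of the DMSO library with the same number, and the ratio of the group means was 12.2. Break ends lay on the same chromosomes in both conditions: relative to its length, chromosome 19 carried 2.31 ± 0.469 (SD, n = 2) times the average density after etoposide and 2.01 ± 0.348 in DMSO. Chromosome 20 carried 2.08 ± 0.168 and 1.95 ± 0.174, chromosome 17 carried 1.95 ± 0.255 and 1.82 ± 0.147, and chromosome 22 carried 1.84 ± 0.349 and 1.57 ± 0.277. Chromosome 4 was at 0.630 ± 0.0755 and 0.680 ± 0.0735. The densest 1 Mb of the etoposide libraries was chromosome 20, 61000001 to 62000000 (GRCh37), with 3660 ± 1446 break ends per 1000000 of the library (EPM; n = 2) against a median of 219 over 2884 bins, and the same bin had 2545 ± 907 in DMSO. Its neighbours on chromosome 20, starting at 62000001 and 60000001, followed with 2975 ± 1110 and 2590 ± 835, ahead of chromosome 9 from 139000001 (2498 ± 1010) and chromosome 17 from 79000001 (2398 ± 973). These bins and chromosomes were singled out after their values were seen.

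The exact two-sided permutation test of the totals gave p = 0.333, the smallest that 2 libraries against 2 can give. The number of cells behind each library is not stated, so the ratio of break ends is a ratio of library yields and not of breaks per cell. For 3 of 23 chromosomes (1 to 22 and X) the shares of the groups did not overlap, 2 higher and 1 lower after etoposide, where chance alone separates groups of 2 in 33.3% of cases. Between libraries of the same replicate number, the share moved in the same direction in replicates 1 and 2 for every chromosome but 10, 15 and 21. Chromosome 19 had 1.12 and 1.17 times its DMSO share, and chromosome 4 had 0.934 and 0.918 times. The labels do not say whether these numbers mark pairs, and this was not tested.

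**Figure D1:**
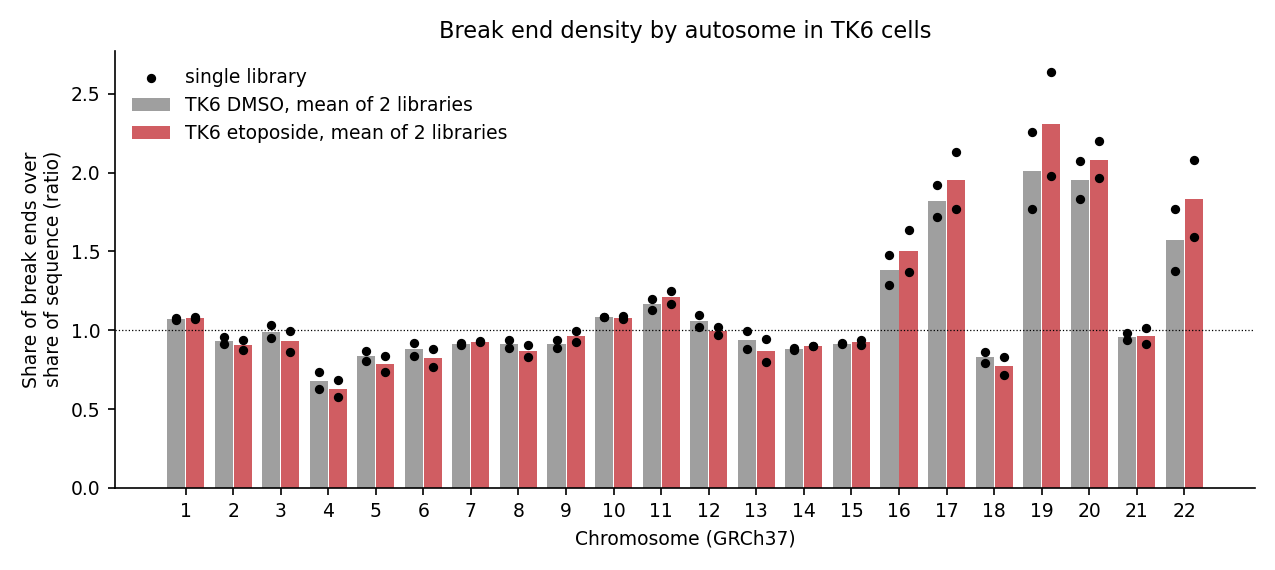
Share of nuclear break ends divided by the share of sequence for each autosome (y axis, ratio) in TK6 cells; bars are means of 2 libraries, points are single libraries, and the dotted line marks the average density. Chromosomes 1, 10, 11, 16, 17, 19, 20 and 22 stood above the average in all 4 libraries, and chromosome 19 reached 2.31 after etoposide.

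Single 1 kb windows collected break ends in all 4 TK6 libraries. Of the 1000 windows with most break ends, the etoposide libraries shared 721 (72.1%, Wilson 95% interval 69.2 to 74.8), the DMSO libraries 34.9%, and a DMSO and an etoposide library 37.9% to 45.5%, where chance gives 0.0414%. Chromosome 20 held 72 of the 721 shared windows, 4.32 times its share of all windows with break ends, and chromosome 18, lowest of the autosomes, held 2, or 0.103 times. Chromosomes 3 and 13 were at 1.52 and 1.63 times; the copy number of chromosomes in these cells was not measured here, so these ratios are not per copy. The windows with highest EPM after etoposide were chromosome 21, 9827001 to 9828000 (385 ± 161, against 2066 and 484 in the DMSO libraries), chromosome 17, 33478001 to 33479000 (382 ± 210, against 3858 and 967), and chromosome 12, 20704001 to 20705000 (196 ± 89.8, against 3804 and 942). With every library thinned to 585021 break ends, the etoposide libraries shared 26.2%, the DMSO libraries 29.0%, and a DMSO and an etoposide library 19.3% to 33.6%, so the higher sharing after etoposide went with depth. Without a genome sequence it was not tested whether reads map uniquely to these windows, which leaves their break ends uncertain.

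Relative to the other break ends of each library, 4 of 27972 bins of 100 kb fell after etoposide and 0 rose (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Unscaled, each of the 4 held more break ends after etoposide than in the DMSO library of the same number. The chromosome X bin had 229 and 73 against 150 and 22, in libraries 10.6 and 15.3 times as large. The falls are thus relative to the larger libraries and not falls in the number of break ends. On chromosome X, 108200001 to 108300000, DMSO had 79.0 ± 59.3 counts per 1000000 (CPM) and etoposide 14.3 ± 5.52 (n = 2 each), a log2 fold change of -2.53 (SE 0.30, adjusted p = 3.66e-13). The bin on chromosome 19 from 24100001 fell by 2.11 on the log2 scale (SE 0.32, adjusted p = 3.33e-07), and that on chromosome 20 from 26100001 fell by 1.33 (SE 0.26, adjusted p = 0.00184). The bin on chromosome 11 from 85100001 fell by 2.13 (SE 0.40, adjusted p = 0.000895). Its libraries overlapped (105 ± 108 CPM in DMSO), and it was added to the named bins after its values were seen. The p of these bins rest on a spread estimated over all bins. They do not measure the wide spread of each bin between the DMSO libraries. One 1 kb window held 94.0% to 95.5% of the break ends of the chromosome X bin in DMSO and 61.6% to 69.9% after etoposide. Outside that window the bin had 5.01 ± 4.67 EPM in DMSO and 4.57 ± 2.04 after etoposide. On chromosome 11 the window held 82.4% to 94.2% in DMSO, and the rest of the bin had 8.57 ± 4.87 and 12.5 ± 5.84 EPM. The rest of the chromosome 19 bin had 25.8 ± 17.1 EPM in DMSO and 14.03 ± 1.49 after etoposide, and that of the chromosome 20 bin 22.7 ± 17.6 and 8.70 ± 2.495.

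No higher bin passed in this test, in which 576 of 27972 bins had an unadjusted p under 0.05, a smaller share than the 0.05 that chance alone gives. DESeq2 called 0 higher and 3 lower, 1 of them among the 4. With the replicate number as a block 25 bins passed, 7 higher and 18 lower. In that fit 3394 of 27972 had an unadjusted p under 0.05, a larger share than chance alone gives. The small share above thus belongs to the fit without a block, and whether the replicate numbers mark pairs is not known. In 1 Mb bins 5 passed, 1 higher and 4 lower. The calls depended on single libraries: without DMSO replicate 1 no bin was called (250 at p under 0.05) and the bins on chromosomes X, 19, 20 and 11 had -1.35, -0.97, -0.58 and -0.18, and without etoposide replicate 1 there were 106, of which 87 were higher and 19 lower.

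The spacing of break positions was compared within TK6 cells. Pairs of positions 1 bp apart were 4.20 ± 0.0396 (SD, n = 2) times as frequent as pairs 50 to 100 bp apart after etoposide and 2.73 ± 0.553 times in DMSO. Pairs 4 bp apart were at 1.78 ± 0.0460 in TK6 etoposide and 1.83 ± 0.151 in TK6 DMSO libraries, and pairs 7 bp apart at 1.34 ± 0.0178 and 1.599 ± 0.0650. Pairs 10 bp apart were at 1.31 ± 0.00252 and 1.46 ± 0.0286. At 170 to 199 bp relative to 120 to 149 bp, the ratio was 1.01 ± 0.00185 after etoposide and 0.972 ± 0.0162 in DMSO. The exact two-sided permutation p was 0.333 for the differences at 1 and 10 bp and in this ratio, the smallest this design allows, and the difference at 1 bp went from 1.47 to 0.851 when positions were weighted by their break ends (exact permutation p = 0.667) and to 3.46 with libraries thinned to equal depth (exact permutation p = 0.333). The files of the TK6 libraries list some positions more than once (26, 2, 7001 and 10322 lines), so that values at 1 bp can carry a trace of how these files were written.

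**Figure D2:**
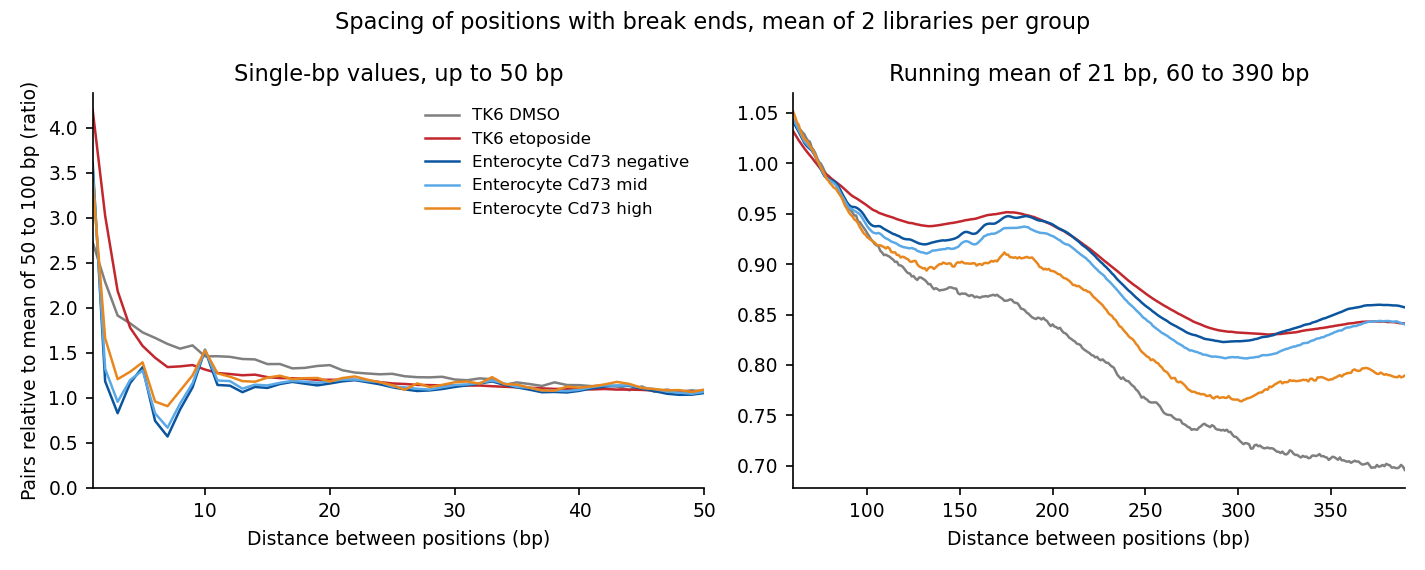
Pairs of positions with break ends at each distance (x axis, bp) relative to the mean over 50 to 100 bp (y axis, ratio), as means of 2 libraries per group, single values to 50 bp on the left and running means of 21 bp on the right. Etoposide stood at 4.20 and DMSO at 2.73 at 1 bp, and between 8 and 13 bp the enterocyte groups were highest at 10 bp.

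The second comparison set Cd73 high enterocytes against Cd73 negative ones, the extremes of the sort. The 33 nutrient absorption genes fell in Cd73 high cells relative to other genes, with a median log2 fold change of -0.26, and 25 of the 33 were negative (adjusted p = 0.472 with an estimated correlation). The 31 genes of common fragile sites, most of them very long, rose by a median of 0.18, with 30 of 31 positive, and 24 neuronal genes rose by 0.23 with 21 positive (adjusted p = 0.472 and 0.3799 with an estimated correlation). With a gene length offset the median of the fragile site genes was -0.07, with 25 of 31 negative. Nt5e itself, the sorted marker, had 51.1 ± 0.104 CPM in negative, 70.3 ± 2.30 in mid and 77.5 ± 17.7 in high cells (n = 2 each). A single gene of 17809 passed on its own, Cdk5rap2, whose product organises microtubules at the centrosome, with 195 ± 13.8 CPM in negative and 320 ± 25.9 in high cells.

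Cdk5rap2 (gene 214444, chromosome 4, 70216855 to 70410435, GRCm38) rose by 0.71 on the log2 scale (SE 0.13, adjusted p = 0.00166, edgeR quasi-likelihood test). A 10 kb window inside the gene, 70370001 to 70380000, held 22.6 ± 0.683 EPM in negative, 38.3 ± 3.08 in mid and 83.3 ± 5.47 in high cells (EPM count the whole library, the CPM of genes only break ends in gene bodies), and without it the gene's log2 fold change was -0.07 (adjusted p = 0.940). The call was also absent when each position was counted once (0.19, adjusted p = 0.970) and without Cd73 negative M2 (0.64), high M1 (0.79) or high M2 (0.63). At an unadjusted p under 0.05 there were 1557 of 17809 genes, a larger share than the 0.05 that chance alone gives. With DESeq2 the number was 703, a smaller share, and it called 1 gene, Cdk5rap2. With the replicate number as a block 44 genes passed, 39 higher and 5 lower.

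Nt5e (gene 23959, chromosome 9, 88327609 to 88372089) had a log2 fold change of 0.62 (SE 0.19, unadjusted p = 0.000861), with an adjusted p of 0.325 over all genes and 0.0120 adjusted over the list alone, the 14 villus tip enterocyte genes. It was 0.34 without Cd73 high M1. Of the same list, Klf4, a transcription factor of differentiated epithelium, had -0.99 (SE 0.34), with 26.8 ± 2.37 CPM in negative and 13.04 ± 6.66 in high cells and 0.0265 adjusted over the list alone; it was -0.60 without high M2 and -1.69 without high M1. So 2 of the 14 passed adjusted over the list alone, 1 in each direction, and 0 over all genes. Klf4 did not pass with positions counted once, with the length offset, thinned or without negative M2, Nt5e did not without high M1, and neither did at gene ends. The list had a median of 0.11 and a camera adjusted p of 0.240, with 9 of 14 positive.

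Among the nutrient absorption genes, the fructose transporter Slc2a5 had -0.76 (SE 0.25), from 46.9 ± 1.95 CPM in negative to 27.7 ± 1.41 in high cells, and the peptidase Ace had -0.67 (SE 0.25), from 44.2 ± 0.356 to 28.3 ± 7.16. Fabp1, the fatty acid binding protein, went against the list at 1.13 (SE 0.41), from 7.89 ± 1.46 to 17.5 ± 3.52. Each of the 3 had 0.0794 adjusted over the list alone, so 0 of 33 passed there or over all genes. The list as a set had a camera adjusted p of 0.00152 over 17 lists with the preset correlation of 0.01, and p = 0.187 (adjusted p = 0.472) with an estimated correlation. Its adjusted p was 0.0538 without Cd73 negative M1, 0.108 without high M1 and 0.864 near gene ends (14 positive, 16 negative). Enterocyte identity genes also fell (median -0.13, 23 of 29 negative, adjusted p = 0.0263; adjusted p = 0.472 with an estimated correlation), and again 0 members passed over all genes or adjusted over the list alone. Their members with the smallest p were the tight junction gene Cldn15 (-1.09, SE 0.50), the keratin Krt8 (-0.71, SE 0.36) and the transcription factor gene Gata6 (-0.37, SE 0.19). That call was absent without negative M1 (0.0538), high M1 (0.160) or high M2 (0.0638).

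Immediate early genes, which respond to stimuli within minutes, fell (median -0.26, 24 of 32 negative, adjusted p = 0.00835; adjusted p = 0.541 with an estimated correlation). Atf3 had -0.81 (SE 0.30), Myc -0.82 (SE 0.34) and Ier2 -0.89 (SE 0.38), and 0 of 32 passed over all genes or adjusted over the list alone. The median was -0.02 when each position was counted once and -0.04 with a gene length offset, and the call was absent in both fits and without negative M2 (0.0977) or high M2 (0.125). Of 30 proliferation genes, 18 were negative (median -0.09, camera adjusted p = 0.240), and with libraries thinned to equal depth the list passed downwards (median -0.20, adjusted p = 0.0433). Mcm7, a subunit of the replicative helicase, had -1.15 (SE 0.34, from 28.4 ± 0.0840 to 12.96 ± 2.88 CPM) and passed adjusted over the list alone (0.0254), 1 of 30, with 0 over all genes. No member passed with positions counted once, with the length offset, at gene ends, or without negative M1, high M1 or high M2. Mcm7 overlaps another gene, so its break ends cannot be assigned to it with certainty.

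The fragile site genes rose with a camera adjusted p of 2.66e-12 (adjusted p = 0.472 with an estimated correlation). Rbfox1 had 0.36 (SE 0.13) and Csmd1, which overlaps another gene, 0.32 (SE 0.13). Across all genes split into 4 equal groups by length, the longest (median 107 kb) had a median log2 fold change of 0.10 and the shortest (5.57 kb) -0.20. The log2 fold change also correlated across genes with break density in mid cells (Spearman -0.43) and with length (0.31). Sparse genes thus tended to rise and dense ones to fall. Neuronal genes rose (adjusted p = 0.000193; adjusted p = 0.3799 with an estimated correlation), led by the neurotransmitter receptor genes Grin2a (0.35, SE 0.13), Gria1 (0.36, SE 0.14) and Gabrb2 (0.37, SE 0.14). None of the members of either list passed over all genes or adjusted over the list alone: 0 of 31 and 0 of 24. With the replicate block, 3 fragile site genes passed over all genes and 14 adjusted over the list alone, and 6 neuronal genes adjusted over the list alone. With the length offset, 2 fragile site genes passed over all genes, 3 passed downwards adjusted over the list alone, and the list passed downwards (adjusted p = 0.000170).

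Among lists of cell types other than enterocytes, tuft cell genes rose (median 0.29, 11 of 14 positive, adjusted p = 0.0189; adjusted p = 0.3799 with an estimated correlation), with Dclk1 at 0.37 (SE 0.14; -2.47 near its gene ends), Rgs13 at 0.56 (SE 0.26) and Vav1 at 0.34 (SE 0.21). Lymphocyte genes rose (median 0.22, 16 of 20 positive, adjusted p = 0.00964; adjusted p = 0.472 with an estimated correlation), with Cd3g at 0.96 (SE 0.43) and Ptprc at 0.33 (SE 0.17). Olfactory receptor genes rose as well among the 81 of 1106 annotated members that passed the count filter (median 0.30, 56 positive, adjusted p = 0.0214, and adjusted p = 0.3799 with an estimated correlation). Their members Olfr1258 (1.27, SE 0.39), Olfr324 (1.72, SE 0.71) and Olfr1006 (1.497, SE 0.66) belong to a large family of similar genes and are uncertain for that reason. The count filter can be passed through the libraries of a single group, and few break ends suffice in the shallow high libraries. Some of the 81 may thus have passed only through high values there, which makes their rise uncertain. In these 3 lists 0 members passed over all genes or adjusted over the list alone. All 3 were less dense in negative cells than lists of the same gene lengths, tuft cell genes least clearly. With positions counted once, tuft cell genes lay at percentile 20.57 of the matched lists, lymphocyte genes at 0.29 and olfactory receptor genes at 0. Camera does not separate their rises from the general rise of sparse genes. The tuft call was absent without negative M1 (0.0538) or high M2 (0.225), and the lymphocyte call without high M1 (0.193). The olfactory call was absent with positions counted once (0.311), with the replicate block (0.0722) and thinned (0.928, the test pointing down), and the tuft and enterocyte identity calls also thinned (0.121 and 0.254). With positions counted once only the nutrient absorption, neuronal and fragile site calls remained, and near gene ends only the lymphocyte and olfactory ones. In all, 8 of 17 lists passed with the preset correlation, 5 up and 3 down, and 0 with an estimated correlation, where the smallest unadjusted p was 0.0281 (neuronal genes) and 1 list was under 0.05.

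The remaining lists did not pass. Medians were 0.02 for 6 villus bottom antimicrobial genes (adjusted p = 0.890), 0.04 for 21 crypt stem cell genes (0.890; the mean and the test had the opposite sign), -0.15 for 13 goblet cell genes (0.542), 0.34 for 3 Paneth cell genes (0.704), -0.08 for 19 enteroendocrine cell genes (0.890), 0.00196 for 20 stromal and endothelial genes (0.542) and -0.08 for 47 ribosomal protein genes (0.328). The antimicrobial genes had a positive median and mean while the test pointed down. In each of these 7 lists 0 members passed over all genes or adjusted over the list alone. Ribosomal protein genes have many near-identical copies, so their values are uncertain.

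**Figure D3:**
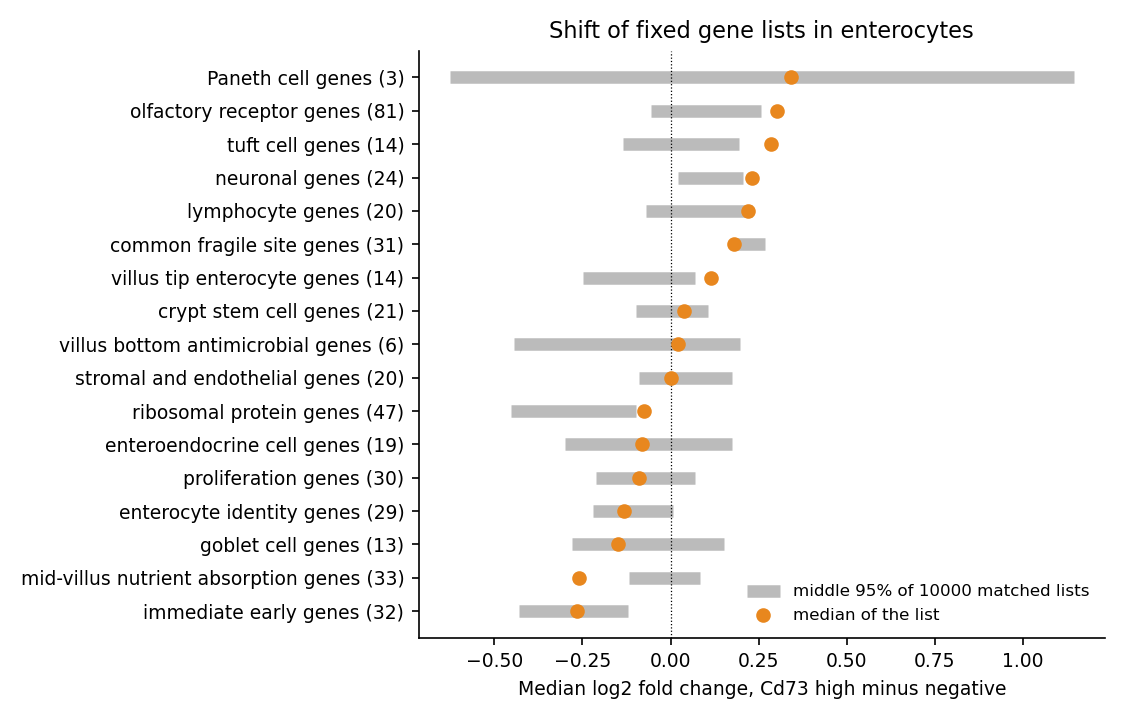
Median log2 fold change of each fixed gene list (x axis, Cd73 high minus negative; number of genes in parentheses) as points, with grey bars for the middle 95% of 10000 random lists matched on gene length and on density in the Cd73 mid libraries. The nutrient absorption genes at -0.26 lay outside their matched range, and the immediate early genes at -0.26 inside it.

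In bins of 100 kb, 7 of 25093 rose in Cd73 high cells and 0 fell. A bin of chromosome 14 from 19400001 went from 98.1 ± 7.31 to 274 ± 14.9 CPM (log2 fold change 1.48, SE 0.27, adjusted p = 0.00513), and one at the start of chromosome 9, from 3000001, from 102 ± 4.38 to 264 ± 39.2 CPM (1.37, SE 0.26, adjusted p = 0.0109). Neither overlapped an annotated protein-coding gene, and whether reads map uniquely to these bins or to the Cdk5rap2 window was not tested, so the rises are uncertain as rises of breaks there. The bin of chromosome X from 87200001, inside Il1rapl1, a synaptic receptor gene, rose by 0.97 (SE 0.14, adjusted p = 9.59e-05). That of chromosome 4 from 70300001, inside Cdk5rap2, rose by 0.98 (SE 0.16, adjusted p = 0.00112). Chromosome 1 from 31300001 (0.82, SE 0.16), chromosome 12 from 48900001 (0.75, SE 0.15) and chromosome 9 from 3200001 (0.86, SE 0.18) completed the set, all outside protein-coding genes. Outside its 1 kb window of most break ends, the Il1rapl1 bin had 13.7 ± 0.207 EPM in negative and 13.4 ± 2.20 in high cells, and the Cdk5rap2 bin 39.6 ± 2.03 and 39.5 ± 2.97. The other 5 kept a difference there: 63.4 ± 5.58 against 191 ± 21.6 on chromosome 14, 81.2 ± 1.28 against 216 ± 40.4 and 14.2 ± 0.136 against 20.99 ± 1.90 for the first and second bin named on chromosome 9, 23.3 ± 0.128 against 40.0 ± 6.58 on chromosome 1, and 26.0 ± 0.270 against 43.5 ± 2.97 on chromosome 12. At an unadjusted p under 0.05 there were 2598 of 25093 bins (1771 with DESeq2), both larger shares than the 0.05 that chance alone gives. DESeq2 called 7 higher and 0 lower. With positions counted once 4 bins (2 of the 7) passed, with libraries thinned 2, and with the replicate block 11 (8 higher, 3 lower). The count was 1, 4 (1 of them lower), 1 and 0 without negative M1, negative M2, high M1 and high M2.

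**Figure D4:**
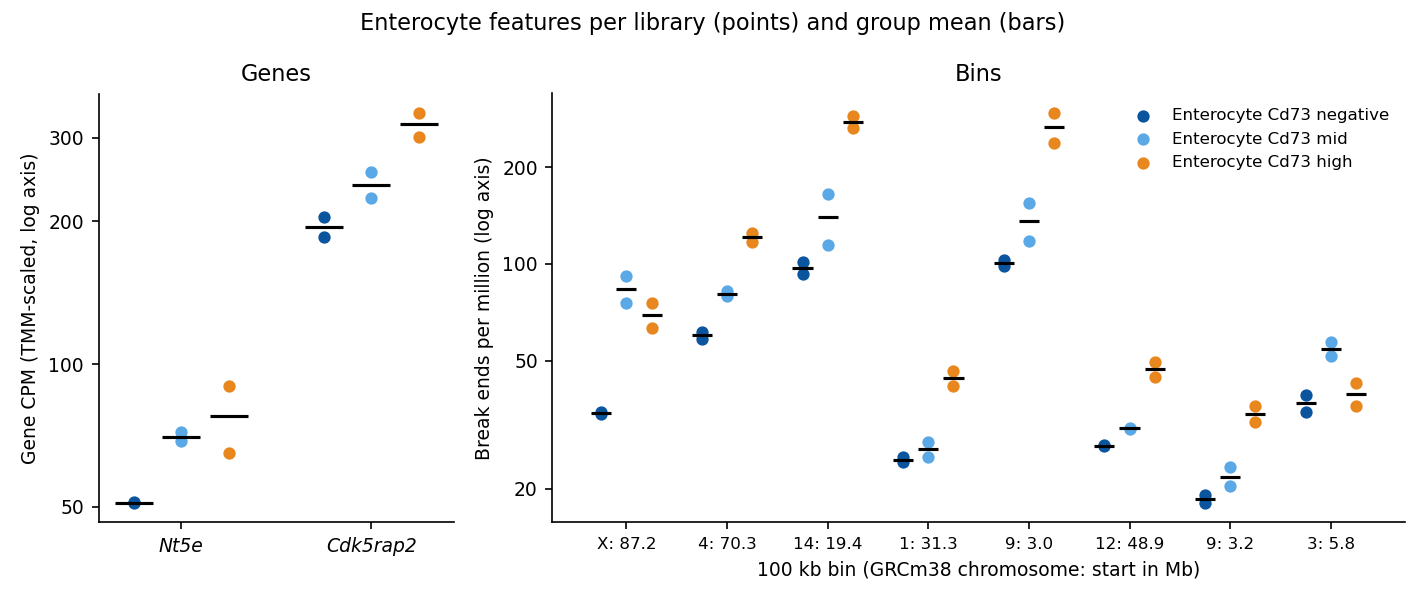
CPM of 2 genes on the left, and EPM in 8 bins of 100 kb on the right (log axes), with points for single libraries and bars for the mean of 2. In the bin of chromosome 14 both Cd73 high libraries stood above every other library, with a group mean of 274 CPM against 98.1 CPM in Cd73 negative.

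Cd73 mid cells were compared with Cd73 negative cells to see whether the intermediate gate already differed. The Il1rapl1 bin on chromosome X rose in mid cells too, from 34.7 ± 0.725 to 83.2 ± 10.3 CPM (log2 fold change 1.26, SE 0.10, adjusted p = 3.96e-14). Outside its 1 kb window of most break ends it had 13.7 ± 0.207 EPM in negative and 14.4 ± 0.971 in mid cells. The whole bin was at 83.4 ± 11.3 EPM in mid and 69.2 ± 8.75 in high cells. A bin of chromosome 3 from 5800001, outside protein-coding genes, rose by 0.54 (SE 0.10, adjusted p = 0.00518). It had 37.0 ± 3.25 EPM in negative, 54.5 ± 3.84 in mid and 39.4 ± 4.63 in high cells. Neither bin thus rose further from mid to high cells. Nutrient absorption genes fell by a median of 0.12, 29 of 33 being negative (camera adjusted p = 0.000308; adjusted p = 0.387 with an estimated correlation). Ribosomal protein genes (median -0.21, adjusted p = 0.00155) and immediate early genes (-0.11, adjusted p = 0.0244) fell too, with adjusted p = 0.387 and 0.529 under an estimated correlation. Fragile site genes (0.10, adjusted p = 0.000156), neuronal genes (0.14, adjusted p = 0.00187), tuft cell genes (0.20, adjusted p = 0.00355) and olfactory receptor genes (0.17, adjusted p = 0.00355) rose, with adjusted p = 0.529, 0.275, 0.275 and 0.275 under an estimated correlation. Nt5e had 0.46 (unadjusted p = 0.00115, adjusted p = 0.998 over all genes) and passed adjusted over the list alone, as did Lck, a T cell kinase gene, at 0.57. No member of any list passed over all genes, and the other lists did not pass as sets. Across all genes the log2 fold change rose with gene length here too (Spearman 0.20). Its median was -0.07 in the shortest and 0.04 in the longest of the 4 length groups. List values with a length offset are not given for this comparison, so these shifts are not separated from that trend. Both comparisons use the same negative libraries, so their values are not independent.

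No gene passed for mid against negative (edgeR quasi-likelihood test), and DESeq2 called 0. At an unadjusted p under 0.05 there were 563 of 17809 genes, a smaller share than the 0.05 that chance alone gives. Of 25093 bins 2 passed, both higher, and DESeq2 called 1. Bins with an unadjusted p under 0.05 numbered 1557, a larger share than chance alone gives, and 471 with DESeq2, a smaller one. With positions counted once, neither of these 2 bins was called. With the replicate number as a block 4 genes passed, 2 higher and 2 lower, and 3 bins, 2 higher and 1 lower. Between Cd73 high and mid cells, 0 genes and 0 bins passed, and DESeq2 called 0 of either. At an unadjusted p under 0.05 there were 804 genes and 1185 bins, both smaller shares than the 0.05 that chance alone gives. Of the lists, fragile site genes rose further in high than in mid cells (median 0.10, 30 of 31 positive, camera adjusted p = 0.000192, and adjusted p = 0.849 with an estimated correlation), and the other 16 did not pass. No value with a length offset is given for this comparison, so that rise is not separated from a trend with gene length. Median and mean differed in sign for villus tip (0.06 and -0.04), villus bottom (-0.01 and 0.00371), crypt stem (0.02 and -0.03), enteroendocrine (0.02 and -0.05) and ribosomal protein genes (-0.01 and 0.03) here, and for villus bottom (-0.17 and 0.00491), proliferation (5.55e-05 and -0.04) and Paneth cell genes (0.00788 and -0.10) in mid against negative.

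Densities of break ends in genes were set against gene length in each gate, without a test between gates. Of the 17 lists, immediate early genes were the densest in negative cells, with a median of 1.85 EPM per kb in negative, 1.73 in mid and 1.37 in high cells, which was 1.76, 1.82 and 1.64 times that of random lists of the same gene lengths. Enterocyte identity genes stood at 1.54, 1.57 and 1.45 times their length-matched lists, nutrient absorption genes at 1.28, 1.197 and 1.11 times, and fragile site genes at 1.19, 1.12 and 1.07 times. Olfactory receptor genes stood at 0.362, 0.449 and 0.507 times and the 3 Paneth cell genes at 0.416, 0.359 and 0.424, and lymphocyte genes at 0.736, 0.757 and 0.904 and neuronal genes at 0.805, 0.806 and 0.891 were low as well. Goblet (0.986), proliferation (0.957) and ribosomal protein genes (0.979) were near 1 in negative cells, and tuft cell genes stood lower at 0.859. Of the 30 densest genes in negative cells, ranked after their values were seen, 3 were members of a list, all immediate early genes: Ier2 had 7.11 ± 0.651 EPM per kb in negative and 3.45 ± 1.23 in high cells, Junb 6.56 ± 2.39 and 4.67 ± 0.0402, and Jun 5.29 ± 1.33 and 5.02 ± 0.477. Genes outside the lists, among them the 3 densest, are not named.

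**Figure D5:**
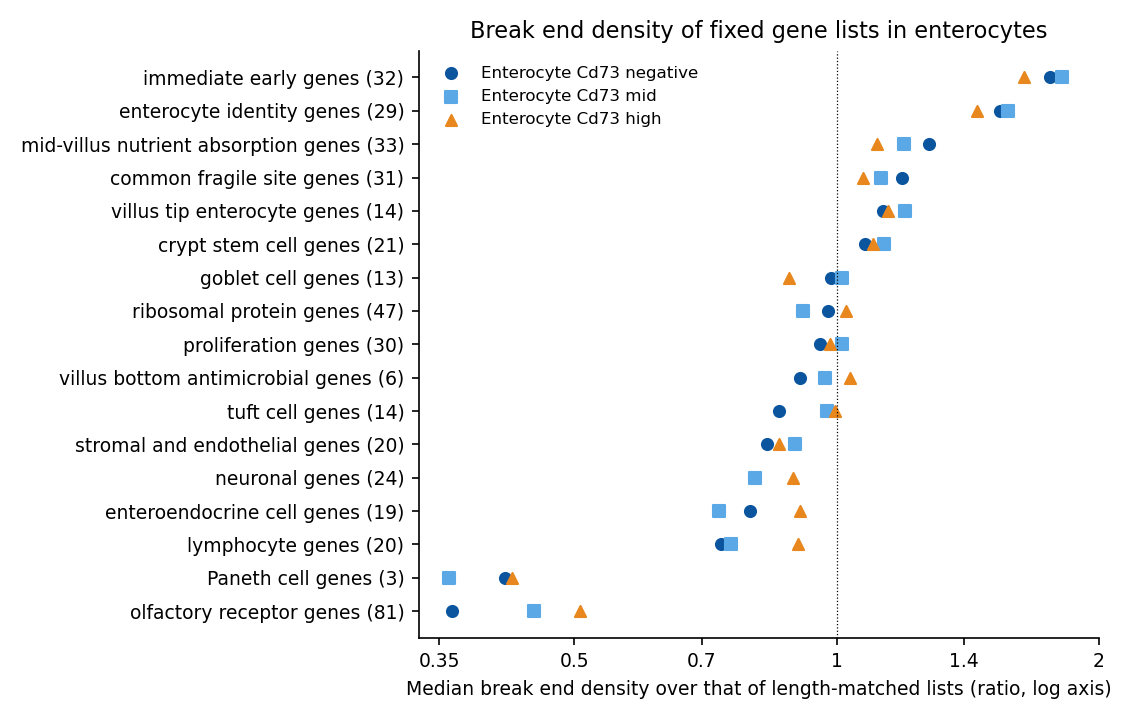
Median break end density of each fixed gene list divided by that of random lists matched on gene length (x axis, ratio, log axis; number of genes in parentheses), with one marker for each Cd73 gate. Immediate early genes stood at 1.64 to 1.82 and olfactory receptor genes at 0.362 to 0.507.

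Break ends gathered at the borders of genes. Within 1 kb of either end of a protein-coding gene, 2.91% of the sequence, lay 8.83 ± 0.944% (SD, n = 2) of break ends in negative, 7.77 ± 1.201% in mid and 6.76 ± 0.334% in high cells. Gene bodies, 37.9% of the sequence, held 49.9 ± 0.689%, 48.9 ± 0.823% and 47.8 ± 0.597%. For high against negative the exact two-sided permutation p was 0.333 for both shares, the smallest possible, and with each position counted once the shares near gene ends were 6.90 ± 0.573% in negative and 6.51 ± 0.274% in high cells (exact permutation p = 0.667).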

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

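The tests of the length trend for the nutrient absorption and fragile site genes, of the Cdk5rap2 window and of mitochondrial DNA were chosen after the results were seen. Break ends outside the nuclear chromosomes, which no comparison used, lay above the limit that a count of 0 allows (0.230 to 2.35 per 1000000 of all break ends) in all 6 enterocyte libraries. Mitochondrial break ends per 1000000 were 89.4 and 55.4 in Cd73 negative, 110 and 113 in mid, and 186 and 327 in high libraries. Break ends on unplaced contigs were 650.03 and 721 per 1000000 in negative, 753 and 895 in mid, and 1037 and 1225 in high libraries.

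Nutrient absorption genes fell in Cd73 high against negative cells (adjusted p = 0.472 with an estimated correlation). With a length offset the median stayed at -0.24, with equal depth it was -0.28, and it lay at percentile 0 of matched random lists. Gene length, depth and a flatter break profile thus did not account for the whole measured median. The random lists treat genes as independent, and the list did not pass with an estimated correlation or near gene ends. Whether there is a fall beyond the spread of the libraries therefore stays open. GC content could not be tested without a sequence, and the Cd73 gate stays open as an untested biological explanation.

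Fragile site genes rose (adjusted p = 0.472 with an estimated correlation). With the length offset their median was -0.0743 and the list passed downwards (adjusted p = 0.000170), so the general shift towards long genes may account for the rise. Against lists matched on length and density they stood at percentile 1.94, having risen less than these lists, an outcome outside both that had been set down for a flatter break profile. That explanation therefore stays open, as does the Cd73 gate, which was not tested.

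The rise of Cdk5rap2 may rest on a single 10 kb window, since the log2 fold change was -0.0667 without it, and on few positions holding many break ends, since it was 0.19 with each counted once, close to the bound of 0.2. The call remained with positions over 100 break ends left out, so positions that high do not account for it. Positions with fewer break ends were not left out in turn. Mitochondrial DNA mapped to the window would keep the ratio of window to mitochondrial break ends alike in all libraries. The highest ratio was 1.73 times the lowest (counting error 0.22), above the bound of 1.3 by under 2 counting errors, and the window also holds ordinary nuclear ends, which keeps this open. The gate itself was not tested against these.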

How the results depend on the processing

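Settings chosen after the data were seen were the gene length offset, the gene end windows, the gene bodies with 1 kb on each side, the list fits with the block or thinning, the window left out of Cdk5rap2, and all settings of the spacing, gene end, gene body and further enterocyte bin results; for all changes below the cause was not tested. Of 354 recomputed values of the 26 named genes, 342 kept direction and side of the threshold; 25 of these genes had not passed to begin with. Of 186 values for the 17 lists, 126 did, but of 88 for the 8 lists past the threshold only 45, and 41 weakened. TK6 bins numbered 4, but 11 by library size, 7 without the filter, 8 with positions counted once, 1 in 10 kb bins and 5 (1 higher) in 1 Mb bins; leaving out a library gave 0 (DMSO 1) to 106 (etoposide 1). Bins for high against negative numbered 7, but 4 with positions once (2 of the 7), 2 thinned and 2 in 10 kb bins; leaving out a library gave 0 (high M2) to 4. For mid against negative they numbered 2, but 2 others with positions once, 1 thinned, 1 in 10 kb bins, 1 in 1 Mb bins and 1 by DESeq2 (1 to 3 without a library; 1 without negative M1 or mid M1), and for high against mid 0, but 3 with positions once, 1 thinned and 2 in 1 Mb bins (0 to 1, mid M1). Genes for high against negative numbered 1, but 0 by library size, without the filter, thinned and at gene ends, 1 other with positions once, and 5 with the length offset (0 to 2 without a library; 0 without negative M2, high M1 or high M2). For mid against negative they were 0, but 1 with positions once. The labels do not say whether replicate numbers mark pairs. Deviations of same-numbered libraries correlated at 0.51 in TK6, which leaves pairing open there, and at 0.34, -0.04 and -0.05 in enterocytes. With the replicate block the counts were 25 (7 higher) for TK6 bins, 11 (8 higher, 3 lower) and 2 for high against negative and high against mid bins, 44 (39 higher) and 4 for high and mid against negative genes, and 16 and 24 with length offset and replicate block.

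Lists past the threshold numbered 8, but 0 with an estimated correlation, 0 by fry, 3 with positions once and 2 at gene ends (5 to 7 without a library; 5 without negative M1, high M1 or high M2). Directions reversed as follows. Positions once: enteroendocrine 0.00188, ribosomal protein 0.15. Length offset: crypt stem -0.0457, fragile site -0.0743, ribosomal protein 0.20. Stromal genes were -0.00325 with the replicate block and -0.0288 thinned. Gene ends: enterocyte identity 0.0636, goblet 0.24, enteroendocrine 0.21, ribosomal protein 0.0275 and Dclk1 -2.47. Cdk5rap2 was -0.0667 without its window. Without a library, medians ranged from -0.16 to 0.11 (villus bottom), -0.0524 to 0.0724 (crypt stem), -0.27 to 0.0499 (goblet), -0.13 to 0.0372 (enteroendocrine) and -0.0367 to 0.14 (stromal). The share near gene ends differed by -2.07, but by -0.39 with positions once (-2.74 to -1.40 without a library), and that in gene bodies by -2.11, but by -1.002 (-2.59 to -1.62). The TK6 difference at 1 bp was 1.47, but 0.851 weighted and 3.46 thinned (1.08 to 1.86). Hotspot sharing was 72.1%, but 65.5% with positions once, 64.5% and 74.84% for the top 200 and 5000, and 26.2% thinned. The TK6 ratio of 12.2 ranged from 9.43 to 17.4 (without DMSO 1). Paneth genes gave no value when thinned. Not run were TK6 genes, human lists and start-site shares (no annotation used here), GC offsets (no sequence), and strand offsets, upstream and start-site windows (no strand).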

Other observations

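Break positions in enterocytes had preferred short distances to one another. All spacing tests here were chosen after the profiles were seen. Within the ranges searched, which were set after the profiles were seen, maxima lay at 5, 10 and 33 bp in all 6 enterocyte libraries, with further ones between 42 and 44 bp. Maxima also lay at 21 or 22 bp in every enterocyte library but Cd73 high M1. There the highest value was at 18 bp, the edge of the range searched, so that library showed no maximum there. The mean over 9 to 11 bp relative to its flanks was 1.26 ± 0.00260 (SD, n = 2) in Cd73 negative, 1.24 ± 0.0236 in mid and 1.17 ± 0.00592 in high cells, while TK6 cells, with their highest value of the first 10 bp range at 9 bp in all 4 libraries, had 0.980 ± 0.0124 after etoposide and 0.983 ± 0.00505 in DMSO. For high against negative the exact two-sided permutation p was 0.333, the smallest possible, and weighted by break ends the values were 0.930 ± 0.0282 and 1.21 ± 0.0350. Broad maxima lay at 174 to 187 bp and 369 to 386 bp in enterocytes, and at 178 and 175 bp and 379 and 367 bp after etoposide. In DMSO the highest values lay at 150 and 170 bp and at 330 and 351 bp, those of replicate 1 at the edge of the range searched, so that library showed no maximum there. The species also differ in how their files were written, so tissue and file cannot be compared apart.

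Mean mitochondrial break ends were 72.4 ± 24.03 per 1000000 of all break ends (SD, n = 2) in Cd73 negative, 112 ± 1.98 in mid and 256 ± 100.05 in high cells, and those on unplaced contigs 686 ± 50.3, 824 ± 100.2 and 1131 ± 133.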
